A study of Mus musculus with 10 samples.

How the data were processed

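Retinas of C57BL/6J mice were collected at postnatal day 34, after 10 days with a -20 D lens on 1 eye. Per the labels, small RNA was isolated with a column kit (miRNeasy mini) and libraries were made from 50 ng of small RNA with the TruSeq Small RNA kit, which ligates adapters to both ends of short RNAs. Adapter ligation favours some sequences over others, so the counts of different miRNAs are not on 1 molar scale, whereas the same miRNA can be compared between libraries.

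Partek, Bowtie and the builds GRCm38 and mm10 are named in the submitters' processing notes, without versions. How adapters were trimmed, which miRNA annotation was used and how reads of identical mature sequences were assigned are not given in the sources used here. The deposited values were a signal derived from read counts, 1 value for each of 1061 mature miRNAs in each of 10 libraries, and the name of the table calls them normalised counts. Sorted from high to low, the values were the same in every library at 342 ranks, and the totals were nearly equal, from 17312269 to 17312436, as quantile normalisation gives. A value therefore reflects the rank of a miRNA in its library. The number of reads per library cannot be recovered from such values, so the depth is unknown, no counting intervals could be given, and a change that left all ranks in place would not be seen. The lowest values are the least precise, and between 822 and 899 miRNAs were above 0 in a library. The smallest value above 0 was 2.81e-36 in the left library of mouse 61 and 0.000147 in that of mouse 68. A value above 0 therefore need not mean that the miRNA was detected. The values of 5 miRNAs were identical in all libraries. The table held 0 columns of other samples.

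Libraries were grouped by the side of the retina and by the number of the mouse, both from the labels. The labels do not say which eye had the lens, so the contrast was right minus left. Both retinas of a number came from the same animal, and mouse was therefore a term of the model. The deviations of the left and right library from the mean of their side correlated across miRNAs, which are not independent replicates, by 0.0893 in mouse 61, 0.382 in 64, 0.159 in 65, 0.295 in 66 and 0.138 in 68, against a median of -0.0824 and a range from -0.338 to 0.355 for eyes of different mice.

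miRNAs with a mean of at least 10 over all libraries were tested, 484 of 1061. Values were taken as log2(value + 1), which understates changes of the lowest miRNAs, and fitted with limma 3.58.1 in R 4.3.3, with mouse as a block, empirical Bayes moderation and a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and fold changes are on the log2(value + 1) scale. There were 21 miRNA lists fixed before the data were examined (photoreceptor, pigment epithelium and neuronal miRNAs, families, and miRNAs of other tissues), and some miRNAs stood in more than 1 list. The 18 lists with at least 3 tested members were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry, which tests whether a list moves 1 way or in either direction without comparing it with other miRNAs. Numbers of miRNAs at 0 and GC trends were compared with an exact sign-flip test over 5 mice, whose smallest possible two-sided p is 0.0625.

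The miRNAs named in the text follow a rule set before the data were examined. It takes up to 12 miRNAs in each direction that pass and have the same direction in all 5 mice, the 10 with the smallest unadjusted p if fewer than 10 pass, the 10 with the highest mean, and from each list the 2 members with the highest mean and any that pass over all miRNAs or over the list alone. This gave 50 miRNAs. Any other miRNA in the text, such as miR-200a-3p, was chosen after its values were seen.

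Positions are those of the deposited table in GRCm38, counted from 1, with the end given as the last base, since the table's end lay 1 base further for 5 of 5 miRNAs of known sequence. Host genes came from the GENCODE annotation of GRCm38. A mature sequence was found in a precursor for 1037 of the 1061 miRNAs and for 482 (99.6%) of those tested, and its GC content was used to check for bias between libraries.

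The fit was tested on simulated data, with 60 of 484 miRNAs changed in each of 20 simulations of the right-minus-left comparison. limma called 49.8% of the miRNAs changed by 1.5-fold, 80.0% of those changed by 2-fold and 93.3% of those changed by 4-fold, and 1.11% of the unchanged ones. In numbers, 96 unchanged miRNAs were called beside 199, 320 and 373 changed ones, a share of false calls above the threshold of 0.05. Of the unchanged miRNAs, 7.34% were at an unadjusted p under 0.05. The list of the Dlk1-Dio3 imprinted cluster, the longest with 34 tested members, was shifted by 0.5 on the log2 scale. It was called by camera in 20 of 20 simulations, and other lists in 1 of 342 tests. No shorter list was shifted, so the power for lists such as retinal pigment epithelium, with 4 tested members, is unknown. The simulated miRNAs varied independently of each other, apart from the normalisation. These rates therefore do not carry over to lists with correlated members, such as the miR-29 family with an estimated correlation of 0.886.

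The alternatives tried were no block, mouse as a random effect (statmod 1.5.0), pseudocounts of 0.5 and 10, trimmed-mean and median-ratio scaling factors, a further quantile step, no filter on the mean, a mean of at least 100, array quality weights, and each mouse left out in turn. Removal of each library's linear trend on GC content, and omission of the miRNAs with 1 value in all libraries, were added after the data had been seen. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.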

Results

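Small RNA was sequenced from the retinas of 5 wild-type C57BL/6J mice, a common inbred laboratory strain. Each mouse had worn a lens of -20 D over 1 eye for 10 days, from postnatal day 24 to postnatal day 34. A minus lens moves the plane of focus behind the retina and is used to induce myopia, and the other eye of each animal had no lens. Both retinas of mice 61, 64, 65, 66 and 68 gave a library each, so that there were 5 left and 5 right libraries. The labels name the side and the mouse of each library but not the side of the lens, so the retinas were compared as right against left within mice and neither side is called treated. The deposited table held normalised read counts of 1061 mature miRNAs. Each library summed to nearly the same total, from 17312269 to 17312436, which is a result of the normalisation, and the sequencing depth of the libraries is unknown. Between 162 and 239 of the 1061 miRNAs were listed at 0 in a library, with 195 ± 33.2 (SD, n = 5) in left and 197 ± 24.4 (SD, n = 5) in right retina (exact sign-flip test over 5 mice, two-sided, p = 1). Per 10 points of GC content of the mature sequence, the log2 values moved by 0.04 ± 0.13 (SD over 5 mice) in right minus left retina (exact sign-flip test, two-sided, p = 0.5).

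A few miRNAs made up most of the retinal profile. miR-182-5p, a sensory-organ miRNA of photoreceptors, was at 9840430 normalised reads and took 56.8% of the normalised total. miR-181a-5p, which is expressed in the inner retina, was at 3689310 normalised reads, a share of 21.3%. miR-183-5p, transcribed with miR-182 and miR-96 as a photoreceptor cluster, followed with 689415 normalised reads and 3.98%. The next in mean level were let-7a-5p with 403943 ± 21171 (SD over 10 libraries), miR-181b-5p with 373816 ± 21171, miR-26a-5p with 280072 and miR-204-5p with 203500 normalised reads. miR-30a-5p and the imprinted miR-127-3p both had a mean of 141170 ± 9779 (SD over 10 libraries), and let-7g-5p had 119506 ± 1973. These 10 miRNAs took 91.7% of the normalised total. By family, both arms of miR-183, miR-96 and miR-182 took 61.04%, the miR-181 family 24.1% and the let-7/miR-98 family 3.88%. The values of miR-182-5p, miR-181a-5p, miR-183-5p, miR-26a-5p and miR-204-5p were identical in all 10 libraries, because the normalisation gave each rank of a library the same value and these 5 miRNAs kept their ranks.

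**Figure D1:**
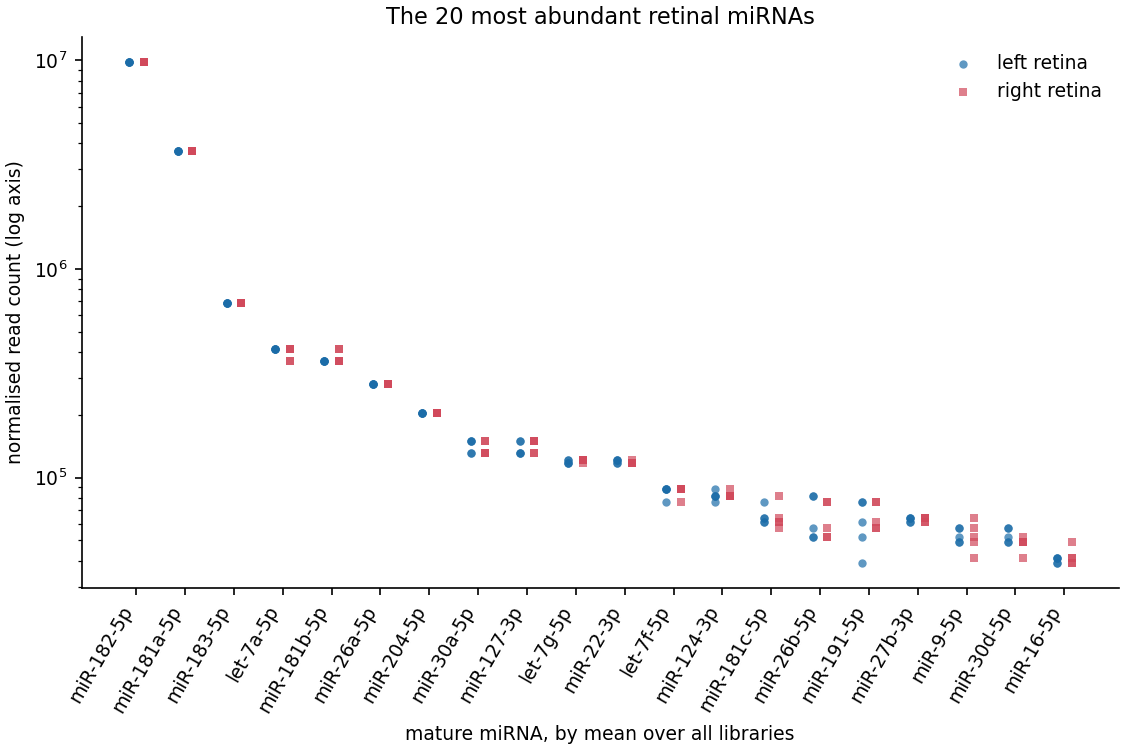
Normalised read counts (log axis) of the 20 most abundant mature miRNAs, with 1 point per library, circles for the 5 left and squares for the 5 right retinas. miR-182-5p stood at 9840430 in each library, and the points of let-7a-5p and miR-181b-5p lie on the same pair of values because the order of these miRNAs was exchanged between libraries.

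The abundant miRNAs came from a small number of loci in the GRCm38 build. miR-182-5p lay on chromosome 6 from 30165962 to 30165986 and miR-183-5p on the same minus strand from 30169711 to 30169732, both outside other annotated genes. miR-181a-5p (chromosome 1, 137966468 to 137966490) lay in an intron of the processed transcript Gm4258, and miR-181b-5p (chromosome 1, 137966650 to 137966673) in an exon of the lincRNA A430106G13Rik. miR-204-5p (chromosome 19, 22750610 to 22750631) lay in an intron of Trpm3, and miR-26a-5p (chromosome 9, 119031811 to 119031832) in an intron of Ctdspl. miR-127-3p (chromosome 12, 109592888 to 109592909) belonged to the Dlk1-Dio3 region, where the 39 listed miRNAs of this imprinted cluster spanned 109585818 to 109743784. For miRNAs with several precursor copies, such as miR-181a-5p, the position is the copy given in the deposited table. Among the 484 miRNAs tested, 231 lay in introns, 111 in exons and 142 outside other annotated genes, and 76 were on chromosome 12.

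The comparison of right with left retina asked which miRNAs differed between the eyes of an animal of which 1 had worn the lens. The levels of the retinal miRNAs were close in both eyes, and no miRNA passed the test. miR-551b-3p had the smallest p and was at 37.3 ± 7.09 normalised reads in left and 21.1 ± 3.84 in right retina (SD, n = 5). It was lower in the right retina of 5 of 5 mice, with a log2 fold change of -0.79 (SE 0.19). The other miRNAs with the smallest p values differed by less, from a log2 fold change of -0.52 for miR-193a-3p to 0.37 for miR-1981-5p. Of the 484 miRNAs tested with limma, 0 were past the adjusted p threshold of 0.05, and the smallest adjusted p was 0.958. At an unadjusted p under 0.05 there were 12 miRNAs, 6 with a higher and 6 with a lower value in the right retina. Chance at the nominal rate gives 24.2, and 7.34% of the unchanged miRNAs were at that level in the simulations.

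miR-551b-3p lies in an intron of Egfem1 on chromosome 3, from 29416879 to 29416899. Of the other miRNAs with the smallest p, miR-376a-5p of the Dlk1-Dio3 cluster (chromosome 12, 109723786 to 109723807, outside other annotated genes) had 98.3 ± 8.47 normalised reads in left and 77.7 ± 8.14 in right retina (SD, n = 5). Its log2 fold change was -0.34 (SE 0.10), and it was lower on the right in 5 of 5 mice. miR-204-3p, the minor arm of the Trpm3-hosted miR-204 hairpin (chromosome 19, 22750649 to 22750669), had 49.1 ± 10.4 normalised reads on the left and 61.9 ± 11.6 on the right, with the right value higher in 5 of 5 mice (log2 fold change 0.33). miR-21a-5p, which is known to increase in inflamed and injured tissue, was measured at 9995 ± 422 normalised reads on the left and 9001 ± 683 on the right. It lies in an exon of Vmp1 on chromosome 11, from 86584120 to 86584141, and its log2 fold change of -0.15 had the same sign in 5 of 5 mice. miR-322-3p, an X-linked miRNA (53054269 to 53054289), also had 1 direction in all 5 mice, with a log2 fold change of 0.29.

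The values of 5 further miRNAs were ordered the same way in 4 of 5 mice. miR-1981-5p (intron of Marc2, chromosome 1, 184822465 to 184822488) had a log2 fold change of 0.37. miR-92b-3p, which shares its seed with miR-92a and miR-25, had a log2 fold change of 0.33 (chromosome 3, 89227126 to 89227147, outside other annotated genes). For miR-193a-3p (chromosome 11, 79712009 to 79712030) and miR-135a-5p (chromosome 9, 106154140 to 106154162) the log2 fold changes were -0.52 and -0.38. miR-486a-5p, an erythroid miRNA in an intron of Ank1 (chromosome 8, 23142587 to 23142608), was at 2686 ± 189 normalised reads in left and 3341 ± 678 in right retina (SD, n = 5). Its mature sequence is the same as that of miR-486b-5p, so that the reads of both cannot be told apart, and the difference may depend on how they were assigned. miR-486a-5p had a log2 fold change of 0.29, and miR-486b-5p of 0.17 with 2923 ± 521 in left and 3270 ± 487 in right retina (SD, n = 5). The difference of miR-486b-5p varied between mice, from -0.30 in mouse 65 to 0.47 in mouse 61. By limma, each of these miRNAs had an adjusted p of 0.958.

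**Figure D2:**
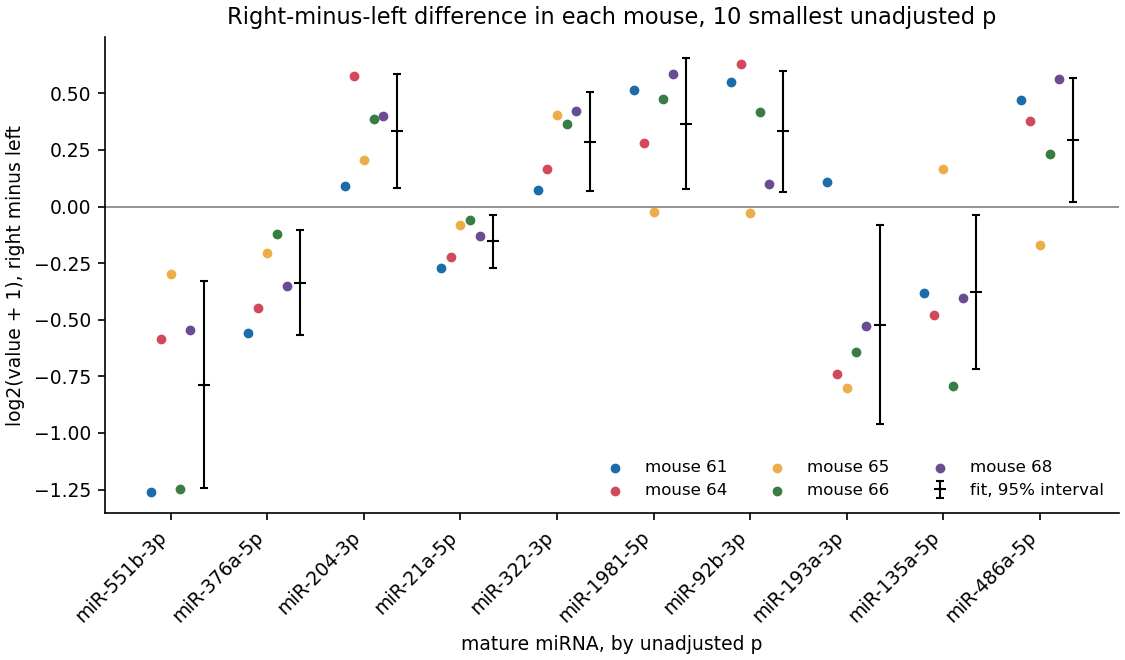
Right-minus-left difference of log2(value + 1) in each of the 5 mice (coloured points) for the 10 miRNAs with the smallest unadjusted p, beside the fitted log2 fold change with its 95% interval (bars). miR-551b-3p lay below 0 in 5 of 5 mice, with a fitted value of -0.79, and miR-204-3p lay above 0 in 5 of 5.

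Of the 484 miRNAs, 18 (3.72%) had the same direction in all 5 mice, where chance gives 6.25% if no difference is 0. A difference of exactly 0 in any mouse kept a miRNA out of this count, so the share by chance is below 6.25% here. The 95% interval of the fold change had a median half-width of 0.34 on the log2 scale, or 1.26-fold, and 437 intervals (90.3%) lay within 2-fold in both directions. A lens effect that sat on the right in some mice and on the left in others would cancel in this contrast. Without mouse 65, 0 miRNAs passed and 63 had an unadjusted p under 0.05.

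No fixed miRNA list passed the test. By limma's camera, 0 of the 18 lists with at least 3 tested members were past an adjusted p of 0.05, and 1 list was at an unadjusted p under 0.05. It was the retinal pigment epithelium list, the miRNAs of the pigmented layer behind the retina. Its 4 members, both arms of the miR-204 and miR-211 hairpins, had a median log2 fold change of 0.28, right minus left. Of these, 3 members were above 0 and miR-204-5p was identical in all libraries. The largest change was 0.38 for miR-211-3p, which moved with miR-211-5p in mice 61 and 64 and against it in mice 65, 66 and 68. The GC content of miR-211-3p is 66.7% and that of miR-204-3p 61.9%, against a median of 50% for the tested miRNAs. The adjusted p of this list was 0.0801 by camera, 0.675 by camera with an estimated correlation and 0.0660 by fry. Adjusted over the list alone, 0 miRNAs passed in each of the 21 lists, with the smallest adjusted p by limma, 0.0707, in the retinal pigment epithelium list. Across the 18 lists, fry gave 0 lists past the threshold in 1 direction and 0 in either direction, with 2 and 1 lists at an unadjusted p under 0.05.

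Among the lists of retinal cells, miR-211-5p, a relative of miR-204 in an intron of Trpm1 (chromosome 7, 64205831 to 64205852), was at 12240 ± 5697 normalised reads in left and 13486 ± 2810 in right retina (SD, n = 5). Its log2 fold change was 0.24 (SE 0.13), and when each mouse was left out in turn it ranged from 0.14 to 0.37. The retinal pigment epithelium list passed without mouse 68, with an adjusted p by camera of 0.0267, and with median-ratio scaling, with 0.0393. With an estimated correlation these adjusted p values by camera were 0.848 and 0.522. In the photoreceptor cluster of miR-183, miR-96 and miR-182, 1 of 6 members lay above 0, 3 lay below and the other 2 were identical in all libraries, with a median of -0.05 and an adjusted p by camera of 0.485. The light-responsive list, which shares miR-183-5p, miR-96-5p and miR-182-5p with that cluster and miR-204-5p and miR-211-5p with the pigment epithelium, had a median of 0.00 (adjusted p by camera 0.869). In the neuronal list, 4 of 12 members were above 0 and 8 below, with an adjusted p by camera of 0.323. miR-124-3p, the most abundant member and a miRNA of mature neurons, was at 81711 ± 4510 normalised reads on the left and 82771 ± 3289 on the right, and miR-9-5p at 53079 ± 4169 and 52742 ± 8563 (SD, n = 5). The 5 members of the neuronal activity list, which holds the activity-induced miR-132-3p and miR-212-3p, all had values below 0, from -0.10 to -0.01 (adjusted p by camera 0.323). miR-132-3p had 2510 ± 413 normalised reads on the left and 2348 ± 359 on the right.

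No list of imprinted or conserved families passed the test in all 5 mice. Of the 34 tested members of the Dlk1-Dio3 list, which leaves out some miRNAs of that cluster such as miR-376a-5p, 13 had a log2 fold change above 0 and 21 below, with a range from -0.26 to 0.19 and an adjusted p by camera of 0.474. Its most abundant members were miR-127-3p, with a log2 fold change of 0.04, and miR-434-3p, with 30350 ± 2820 normalised reads in left and 30403 ± 3604 in right retina (SD, n = 5). In the miR-181 family, miR-181b-5p was at 363774 in all 5 left libraries and at 383858 ± 27502 on the right, and the family had an adjusted p of 0.295 by camera and of 0.0660 by fry. let-7a-5p held the neighbouring rank, with 413985 in all 5 left libraries and 393901 ± 27502 on the right, so that its log2 fold change of -0.07 mirrors the 0.07 of miR-181b-5p. The let-7/miR-98 family had 4 members above 0, 4 below and 1 at 0 (adjusted p by camera 0.836), and the miR-125/miR-99/miR-100 family 4 above and 1 below (0.696). In the latter, miR-125a-5p had a log2 fold change of 0.01 and miR-99b-5p of -0.06.

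All 3 members of the miR-29 family, which represses collagen and other matrix genes, had values below 0, with a median log2 fold change of -0.22 and an adjusted p by camera of 0.295. miR-29c-3p was at 7877 ± 1078 normalised reads in left and 7217 ± 1040 in right retina and miR-29a-3p at 3467 ± 720 and 2941 ± 254 (SD, n = 5). Mouse 65 had the opposite direction for both, and without it the family passed with an adjusted p by camera of 0.00616. With an estimated correlation the adjusted p by camera was 0.614 without mouse 65 and 0.675 in all 5 mice. The members have a GC content of 34.8% to 40.9%, and the GC trend of mouse 65 ran against that of the other mice. With the GC trends removed, in a test chosen after the data were seen, the median difference of the family went from 0.45 to 0.22 in mouse 65 and from -0.78 to -0.54 in mouse 61, and the adjusted p by camera without mouse 65 was 0.00998, or 0.483 with an estimated correlation. In the miR-30 family, 2 members lay above 0 and 3 below (adjusted p by camera 0.303), and the values of miR-30d-5p were 53079 ± 4169 and 48166 ± 4093 normalised reads on the left and right (SD, n = 5). The miR-17-92 family had 3 members above and 6 below 0 (adjusted p by camera 0.537), with miR-92a-3p at a log2 fold change of 0.06 and miR-25-3p at -0.03.

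**Figure D3:**
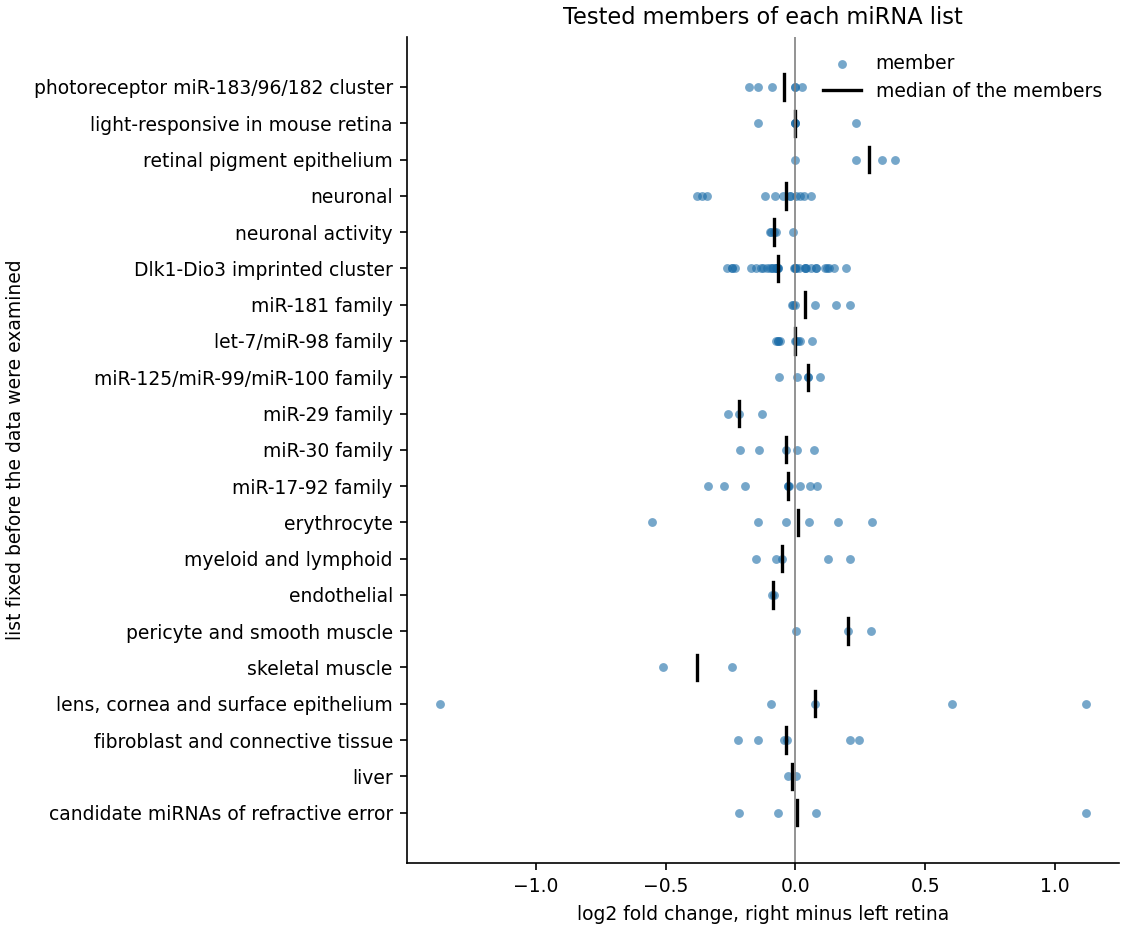
Log2 fold change, right minus left retina, of each tested member (points) of the 21 fixed miRNA lists, with the median of each list as a vertical bar. The retinal pigment epithelium list has a median of 0.28 and the miR-29 family of -0.22, and the widest spread is in the lens, cornea and surface epithelium list, where miR-200a-3p lies at -1.37, with a difference of -4.41 in mouse 68 and of -1.39 to 0.05 in the others, and miR-184-3p at 1.12, with 4.50 in mouse 65.

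miRNAs of blood, vessels and other tissues were measured as well. In the erythrocyte list, 3 members were above and 3 below 0 (adjusted p by camera 0.559, direction up with a median of 0.01 and a mean of -0.04), with miR-16-5p at 40275 ± 1210 normalised reads on the left and 41890 ± 4251 on the right (SD, n = 5). The myeloid and lymphoid list had 2 members above and 3 below 0 (adjusted p by camera 0.869, direction down with a median of -0.05 and a mean of 0.01). Its member miR-150-5p, a miRNA of mature lymphocytes, had a log2 fold change of 0.12, with 0.35 in mouse 61, 0.40 in mouse 64 and -0.16 to 0.05 in the others. The endothelial miR-126a-3p and miR-126a-5p, from an exon of Egfl7, had log2 fold changes of -0.09 and -0.08. In the pericyte and smooth muscle list, 3 of 3 members were above 0 (adjusted p by camera 0.295), with miR-143-3p at 0.00 and miR-145a-5p at 0.29. The fibroblast and connective tissue list had 2 members above and 4 below 0 (adjusted p by camera 0.537, direction up with a median of -0.04 and a mean of 0.00), and its leading members miR-199a-3p and miR-199b-3p, which share 1 mature sequence, had log2 fold changes of 0.24 and 0.21, and the first fell to 0.14 without mouse 68 and the second to 0.12 without mouse 66. The liver list, with 2 tested members, was at 0.00 for miR-192-5p and -0.03 for miR-194-5p.

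In 2 of these lists a single library set the value. The skeletal muscle miRNA miR-133a-3p was at 1596 normalised reads in the left retina of mouse 68 and between 241 and 359 in the other 9 libraries, and miR-133b-3p was at 113 there and between 22.5 and 67.0 elsewhere. The log2 fold change of miR-133a-3p was -0.51 (SE 0.44) over 5 mice and 0.04 without mouse 68. miR-184-3p, which is abundant in lens and cornea and is mutated in a familial eye disorder, was at 22384 normalised reads in the right retina of mouse 65 and between 1898 and 2117 in the other right retinas. Its log2 fold change of 1.12 (SE 0.67) was 0.28 without mouse 65. It lies on chromosome 9 from 89802263 to 89802284, outside other annotated genes, and its list of lens, cornea and surface epithelium had 3 members above and 2 below 0 (adjusted p by camera 0.915, direction down although the median was 0.08). miR-203-3p of the same list was at 218 ± 13.9 normalised reads on the left and 203 ± 9.48 on the right (SD, n = 5).

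The list of candidate miRNAs of refractive error, which holds miR-184-3p, miR-29a-3p, let-7i-5p and miR-328-3p, had 2 members above and 2 below 0 and an adjusted p by camera of 0.915. miR-328-3p, a regulator of the eye gene Pax6, was at 5939 ± 1108 normalised reads in left and 6264 ± 1068 in right retina (SD, n = 5), a log2 fold change of 0.08 (SE 0.16). let-7i-5p had 12500 ± 3152 on the left and 11695 ± 1268 on the right, a log2 fold change of -0.07. Both values turn on single mice, since without mouse 65 the log2 fold change of miR-328-3p was 0.26 and that of let-7i-5p 0.05, and without mouse 61 that of miR-328-3p was -0.02. The 95% intervals of the fold changes reached from -0.30 to 0.46 for miR-328-3p, from -0.57 to 0.13 for miR-29a-3p and from -0.32 to 0.19 for let-7i-5p. For miR-184-3p the interval was far wider, from -0.50 to 2.74.

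**Figure D4:**
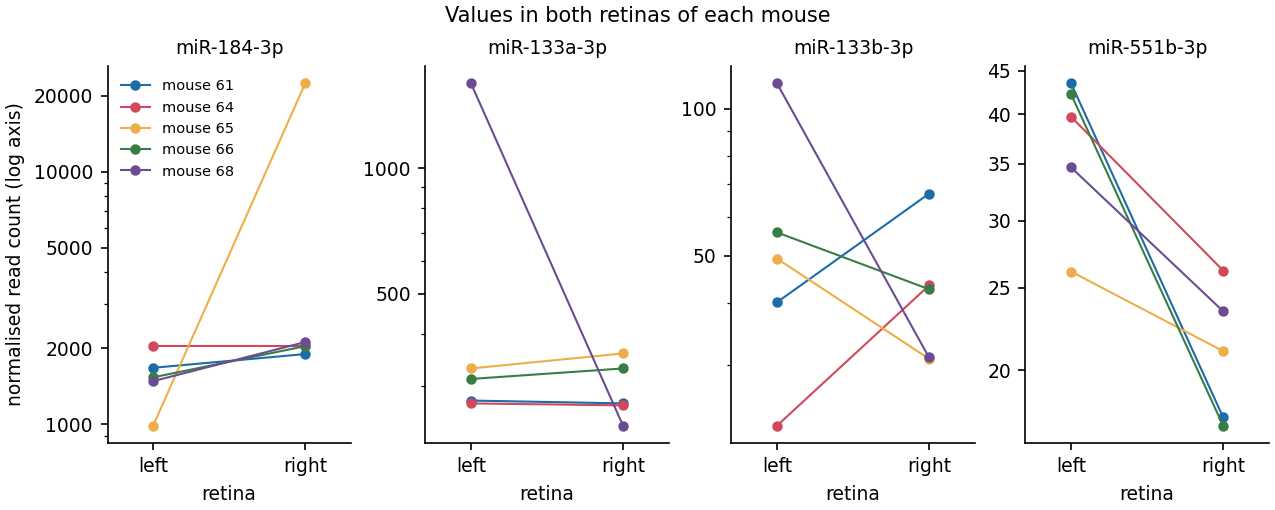
Normalised read counts (log axes) of 4 miRNAs in the left and right retina of each mouse, with 1 line per mouse. miR-184-3p reaches 22384 in the right retina of mouse 65 and miR-133a-3p 1596 in the left retina of mouse 68, whereas miR-551b-3p is lower on the right in all 5 mice.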

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

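The tests on mouse 65 and on miR-184-3p were chosen after the values had been seen, and so was the count of exchanges at unadjusted p. Of the 90 groups of 5 libraries looked at, 8 held a library far from the other 4, where chance gives about 4.5. miR-133a-3p stood apart at 1596 normalised reads in the left retina of mouse 68. In that library all 4 muscle miRNAs were at their highest, with miR-133b-3p at 113, miR-1a-3p at 26.6 and miR-206-3p at 6.29. Over the median of the other 9 libraries, the excess of miR-1a-3p was 1.83% of that of miR-133a-3p and the excess of miR-133b-3p 5.29%. Among left retinas miR-203-3p was lowest there, with 194 against 219 to 228 in the others, but the right retinas were at 203 ± 9.48 (SD, n = 5). In the right retina of mouse 65, let-7g-5p was at 117214 against 121034 in the other 4 right retinas, but the left retinas of mice 65, 66 and 68 were at 117214 too. In the same right retina miR-124-3p was at 88655 against 81300, but the left retina of mouse 68 was at 88655 too. For miR-30d-5p the right retina of mouse 61 was lowest, with 41158 against 49233 to 51974. For miR-16-5p the right retina of mouse 68 was highest, with 49233 against 38949 to 41158. For miR-126a-3p the right retina of mouse 64 was lowest, with 1535 against 1800 to 1898.

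miR-184-3p of lens and cornea stood apart with 22384 normalised reads in the right retina of mouse 65 and 988 in its left retina, a log2 difference of 4.50 where the other right retinas held 1898 to 2117. The difference was 4.51 after each library's GC trend was removed, but this could not test a GC bias. miR-184-3p has a GC content of 50%, the median of the tested miRNAs, so the removal hardly moves it whatever the bias. Lens, corneal or surface epithelium in this retina may be the source, and the other 4 tested members of that list had a median right-minus-left difference of 0.28 in mouse 65, against -0.68 to -0.02 in the other mice. In mouse 65 these members differed by 1.15 for miR-205-5p, 0.61 for miR-141-3p, -0.04 for miR-203-3p and -0.09 for miR-200a-3p, and miR-31-5p, another epithelial miRNA, not in the list and picked after its values were seen, was at 1535 against 244 to 336. This source cannot be told apart from a change of miR-184-3p within the retina, because the list has few tested members and a single library shows the rise, and no biological explanation was tested.

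Exchanging the left and right label within mice gives 16 arrangements of the 5 pairs, too few for a share under 0.05. The labelled arrangement gave 0 miRNAs past the adjusted p threshold by limma, as did all 16 arrangements, and the highest of the others was 0. At an unadjusted p under 0.05 the labelled arrangement gave 12 miRNAs and the highest of the others 95, and 11 of the 16 gave at least as many as the labelled one. For the lists, the labelled arrangement gave 0, all 16 gave at least as many, and the highest of the others gave 3.

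The arrangement with 95 miRNAs was that with the eyes of mouse 65 exchanged, several times the labelled count, and 0 of them passed the adjusted threshold. How high the highest count would be by chance was not tested, so a structure of the samples was not shown. Its 48 higher miRNAs had a median GC content of 57.1% and its 47 lower ones of 40.9%, and per 10 points of GC the right-minus-left difference moved by -0.17 in mouse 65 and by 0.18 in mouse 61, 0.12 in 64, 0.05 in 66 and 0.05 in 68. A linear GC bias as the whole cause is argued against, since 79 miRNAs were at that level with the GC trends removed, and 49 of these were among the 95, whose median difference went from 0.33 to 0.22 in size. Exchanged labels, or a lens on the other side in mouse 65, may also give such a count, and exchanging a second mouse as well should then lower it. The count was 31 with mouse 64 exchanged as well, 46 with mouse 68 and 79 with mouse 66, against 95 for mouse 65 alone. With the GC trends removed these counts were 28, 33 and 71, against 79. Exchanging mice 61 and 65 is the same contrast as exchanging mice 64, 66 and 68, which gave 13, or 12 with the GC trends removed. The count was lower each time, least so with mouse 66, but this could not test the explanation. The arrangement had been picked for its highest count, so all others had to be lower whatever the cause. With the GC trends removed, the difference of mouse 65 correlated across miRNAs by -0.349 with that of mouse 61 and by -0.108 with that of mouse 68. With mice 64 and 66 the correlations were -0.0549 and 0.0448. The other 4 mice correlated with each other by -0.126 to 0.124. Exchanged labels or a lens on the other side cannot be told apart from a property of that pair of libraries, because the labels do not give the side of the lens.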

How the results depend on the processing

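The 2 alternatives on GC content and on miRNAs with 1 value in all libraries were chosen after seeing the data. Under all 17 alternatives, 0 miRNAs were past an adjusted p of 0.05 by limma, as in the analysis reported, and the smallest adjusted p ranged from 0.241 to 1. This includes the fit with no replicate block (0 miRNAs and 0 lists) and the blocked fits with mouse as a random effect or GC trends removed, so the pairing changed no call. The number at an unadjusted p under 0.05 was 12 as reported, 63 without mouse 65, 40 with array quality weights, 25 without the filter on the mean, 19 with mouse as a random effect, and 5 with a mean of at least 100. The number of lists past the threshold by camera was 0 as reported. It was 1 with median-ratio scaling (retinal pigment epithelium, adjusted p 0.0393) and 1 without the miRNAs at 1 value in all libraries (the same list, 0.0193, since miR-204-5p then leaves the list). When each mouse was left out in turn it ranged from 0 to 1, with the retinal pigment epithelium list past the threshold without mouse 68 (0.0267) and the miR-29 family without mouse 65 (0.00616). With an estimated correlation these 4 calls were lost, with adjusted p values by camera of 0.522, 0.506, 0.848 and 0.614 in the order given. The estimated correlation was 0.627 for the miR-29 family. For the retinal pigment epithelium list it was -0.0141, -0.233 and -0.211, below the preset 0.01, so correlated members were not why those calls were lost. Their unadjusted p values by camera with an estimated correlation were 0.0353, 0.0297 and 0.0477. The smallest adjusted p of the lists ranged from 0.00616 to 0.215 over the alternatives. The cause of these calls was not tested, apart from the list that lost a member. Of 838 fold changes of the 50 named miRNAs under alternatives, 822 moved by no more than 1 SD between mice, 16 moved by more, 0 were called and 33, in 14 miRNAs, had another sign. The scalings left the median log2 fold change of all tested miRNAs between -0.01 and 0.00. They acted on values that were already normalised, so they could not test how the results depend on the submitters' normalisation. Depth is unknown, so counting error could not be set apart from differences between animals.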

Other observations

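Within a hairpin, the arm with the higher value was the same in nearly all libraries. The arms are different sequences and ligation favours some of them, so a ratio of arms is not a molar ratio. Both arms could be compared for 104 hairpins, and the 5p arm was higher in every library for 54 and the 3p arm for 44. For miR-182 there were 9840430 normalised reads of miR-182-5p and a mean of 296 of miR-182-3p. For miR-204 the 5p arm had 203500 and the 3p arm a mean of 55.5, and for let-7g 119506 and 23.2. miR-22 and miR-127 had the higher value at the 3p arm, with means of 118742 and 141170 against 66.3 and 318, and so did miR-124, with 82241 for miR-124-3p against 529 for miR-124-5p. The 6 hairpins whose higher arm differed between libraries were miR-296, miR-376b, miR-151, miR-423, miR-345 and miR-322, in all of which the mean log2 ratio of the arms was between -0.85 and 0.83.

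Some miRNAs differed between mice in the same way in both retinas, a comparison chosen, with its tests, after the data were seen. With the mouse term of the limma fit, 8 miRNAs were past an adjusted p of 0.05 and 68 were at an unadjusted p under 0.05. miR-128-3p, a neuronal miRNA, had an adjusted p of 0.00390 by limma and a mean over both eyes of 2078 normalised reads in mouse 61 and 1762 in mouse 68, against 4496 in mouse 64, 4684 in 65 and 4424 in 66. miR-296-3p was at 75.8 and 52.4 in mice 61 and 68 and at 179, 131 and 201 in mice 64, 65 and 66. miR-1964-3p, with means from 10.6 to 71.2, miR-322-3p, miR-329-5p and miR-671-5p also had their lowest means in mice 61 and 68, whereas miR-26b-5p and miR-99a-5p had their highest means in these.

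A candidate explanation is that the animals, or the handling shared by both retinas of an animal, differed in these miRNAs. Matching of left and right libraries at random is argued against, since 0 of the 44 matchings that keep no mouse together gave as many miRNAs, and the highest of them gave 7. A linear GC bias between libraries is argued against too, since 11 miRNAs were past the threshold with the GC trends removed, 6 of them among the original 8, while miR-26b-5p and miR-671-5p then had adjusted p values of 0.0822 and 0.0546 by limma. Litter, sex and library batch of the mice stay open, as the labels used here do not give them.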
